A study of Mus musculus with 2 samples.

How the data were processed

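H3K4me2, the dimethylated form of lysine 4 of histone H3, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in stomach tissue of mouse embryos at day 14.5. Each of the 2 biological replicates was tissue pooled from male and female embryos, per the labels. Sheared fragments of 300 to 500 bp were selected, per the labels. Both replicates form 1 group, and the labels name no second condition, so nothing was compared between groups.

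The values come from 4 deposited peak lists on mm10 (GRCm38). Per the deposited notes that accompany each replicate, the list of each replicate was made from its filtered alignments and its own control, and the pooled list from both replicates' alignments and both controls. The replicated list was derived from the pooled list and both replicate lists, per the same notes, and it holds pooled peaks only: 0 of its entries differ from the pooled list. The aligner, the peak caller, their versions and the calling threshold are not given in the sources used here. Each deposited peak carries a signal value, read here as the fold enrichment over the control that the authors computed; the column's name is not stated in the notes, so this reading follows the file format. The deposited lists also give −log10 p and −log10 q per peak, computed by the authors, and the offset of the summit from the peak's start in bp, another column the authors supplied. Fold enrichment was used to describe, rank or filter peaks within a list, and it was compared between the replicate lists only at replicated peaks that touch both. The lists give no read counts, so the sequencing depth of each library is unknown, and no interval that needs it is given.

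Peaks on chromosomes 1 to 19, X and Y were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes and transcription start sites (TSSs) came from GENCODE M21, with 21938 protein-coding genes and 93513 TSS positions. No peak ran past the end of its chromosome. Coordinates are 1-based. Overlapping intervals were merged before covered length was summed.

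Replicates were compared by the share of peaks that touch a peak of the other by 1 bp or more and by the base-pair Jaccard index, beside 100 random placements of the peaks on the same chromosomes outside assembly gaps (one-sided permutation test, smallest possible p = 0.0099). Summits of replicated peaks were assigned to promoter (within 1000 bp of a protein-coding TSS), exon, intron or intergenic sequence in that order, beside 100 random placements (two-sided permutation test, smallest possible p = 0.0198). Genes were classed by the CpG content of the window 500 bp either side of the TSS. A promoter was of high class where the CpG observed/expected ratio was above 0.75 and GC content above 55%, and low where the ratio was below 0.48. The rest were intermediate. Shares of genes carry 95% Wilson intervals.

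The 16 gene lists, with 263 genes in all, were fixed in advance: gastric mesenchyme, smooth muscle, foregut epithelium, differentiated gastric gland, enteric nervous system, endothelium, mesothelium, blood and immune, intestine, liver, pancreas, cardiac muscle, skeletal muscle, forebrain, germ line and housekeeping. All 264 listed symbols were found, 3 of them through a synonym, and a pair of them named the same gene. Each list was measured in 3 ways in the replicated list: the share of genes with a peak within 1000 bp of any TSS (promoter peak), the median kb covered by peaks within 10 kb either side of the 5'-most TSS (a window of 20.001 kb), and the mean number of distal peaks per gene. A distal peak lies over 1000 bp from every protein-coding TSS and was given to the gene with the nearest TSS within 100 kb. Each measure was set against 10000 random lists of protein-coding genes matched on CpG class (two-sided permutation test, smallest possible p = 0.0002, Benjamini-Hochberg adjusted over the 16 lists). Distal peaks were tested a second time with lists also matched on quintile of territory, the length of genome nearest to each gene, counted up to 100 kb from a TSS. Covered kb counts every peak in the window, including peaks at neighbouring genes, so it is not always the named gene's own. The random lists were not matched on gene density or gene class. Genes are not replicates, so these p-values describe these libraries. Covered kb of genes and lists is also given as mean ± SD of the replicate lists (n = 2).

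Hox genes of paralog groups 1 to 5 and 9 to 13 were compared by the kb covered within 2 kb either side of the TSS (4.001 kb) with a two-sided permutation test over genes, 100000 resamples. For 18 consensus motifs fixed in advance, the central 400 bp of distal peaks were searched on both strands and set against windows of the same GC content (bins of 2%) outside every peak list, by Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 18 motifs. An adjusted p below 0.05 counted as a call. Genes are named by a rule written in advance: up to 4 members of each list with the most covered kb, up to 4 members of each list without a promoter peak, the 20 genes with the most covered kb (1 per overlapping window), the 10 strongest distal peaks, the 10 genes with the most distal peaks, every Hox gene, and list members with a promoter peak in 1 replicate only.

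The statistics were tested on simulated data. Random gene lists without an effect had permutation p below 0.05 in 2.25% of promoter tests, 7.25% of breadth tests and 3% of distal tests. Lists with raised values had p below 0.05 in the raised direction in 100%, 93.5% and 99%. These p-values were not adjusted over lists. The planted rises were large: all genes marked, cover doubled plus 1000 bp, and distal peaks doubled plus 1. The shares therefore do not give the sensitivity of the adjusted calls to smaller effects. The HNF1 motif planted in 5% of 5000 sequences was recovered in 5%. Of the motifs not contained in it 0 were called, and the homeobox motif, which it contains, was left out of that count. Alternatives fixed in advance covered a −log10 q of at least 2, peaks at or above the median fold enrichment, the pooled list, each replicate alone, other overlap rules, other windows, unmatched gene lists and windows beside the peak. The windows beside the peak were not matched on GC content. Peaks on contigs outside the assembled chromosomes were left out of the gene and motif measures and are counted in the closing section.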

Results

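ChIP-seq for H3K4me2, a histone mark of promoters and enhancers, was collected from stomachs of mouse embryos at day 14.5, with 2 biological replicates in 1 group. At this stage the stomach holds a thick mesenchyme that forms smooth muscle, an epithelium that has not yet made mature glands, enteric neurons and blood vessels. Replicate 1 had 41581 peaks over 38.3 Mb and replicate 2 had 54877 peaks over 47.2 Mb, a mean of 42.8 ± 6.27 Mb (SD, n = 2). The pooled list held 53441 peaks over 50.2 Mb. The replicated list, on which the measurements rest unless another list is named, held 35098 peaks over 45.6 Mb, 1.72% of the genome. Its median peak was 1010 bp wide. Read depth is unknown.

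Patterning genes of the stomach mesenchyme were among the genes with the broadest H3K4me2. Meis2, a homeobox gene active in limb and gut mesenchyme (chromosome 2, 115863064 to 116065839), had 19.8 kb of the surrounding 20.001 kb covered in the replicated list, and 19.6 ± 0.238 kb (SD, n = 2) across the replicates. Foxf1, a forkhead factor of gut mesenchyme (chromosome 8, 121084386 to 121088144), had 17.7 kb covered, 16.8 ± 0.195 kb across replicates. Meis1 had 16.4 kb and Nr2f1, a nuclear receptor gene, 16.2 kb. Barx1, a homeobox gene needed in stomach mesenchyme to give the overlying epithelium its gastric identity (chromosome 13, 48662998 to 48666507), had 13.5 kb covered, 13.6 ± 0.938 kb across replicates. All 4 genes with the widest cover in this list, and also Nr2f2, Six2, Barx1, Foxf2 and Isl1, were among the 20 broadest genes of the genome that the naming rule picks.

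The gastric mesenchyme list as a whole had a median of 10.5 kb covered, against 2.55 kb in random lists matched on promoter CpG class, of which 95% lay between 2.02 and 3.24 kb. The adjusted permutation p was 0.0016. Across replicates the list's median was 9.35 ± 1.13 kb (SD, n = 2). Its genes also had the most distal peaks, 4.71 per gene against 0.766 in matched lists (adjusted p = 0.0016, permutation), with 12 near Meis2 and 10 near Nr2f1. Against lists matched on territory as well, the mean to compare was 1.35 per gene (adjusted p = 0.0016, permutation). All 24 genes had a promoter peak, but so did 93.9% of genes in matched lists (adjusted p = 0.538, permutation), so promoter peaks alone did not set the list apart. Fgf10, a growth factor of foregut mesenchyme, had a promoter peak but 0 kb covered around its 5'-most TSS; it was singled out after its values were seen.

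**Figure D1:**
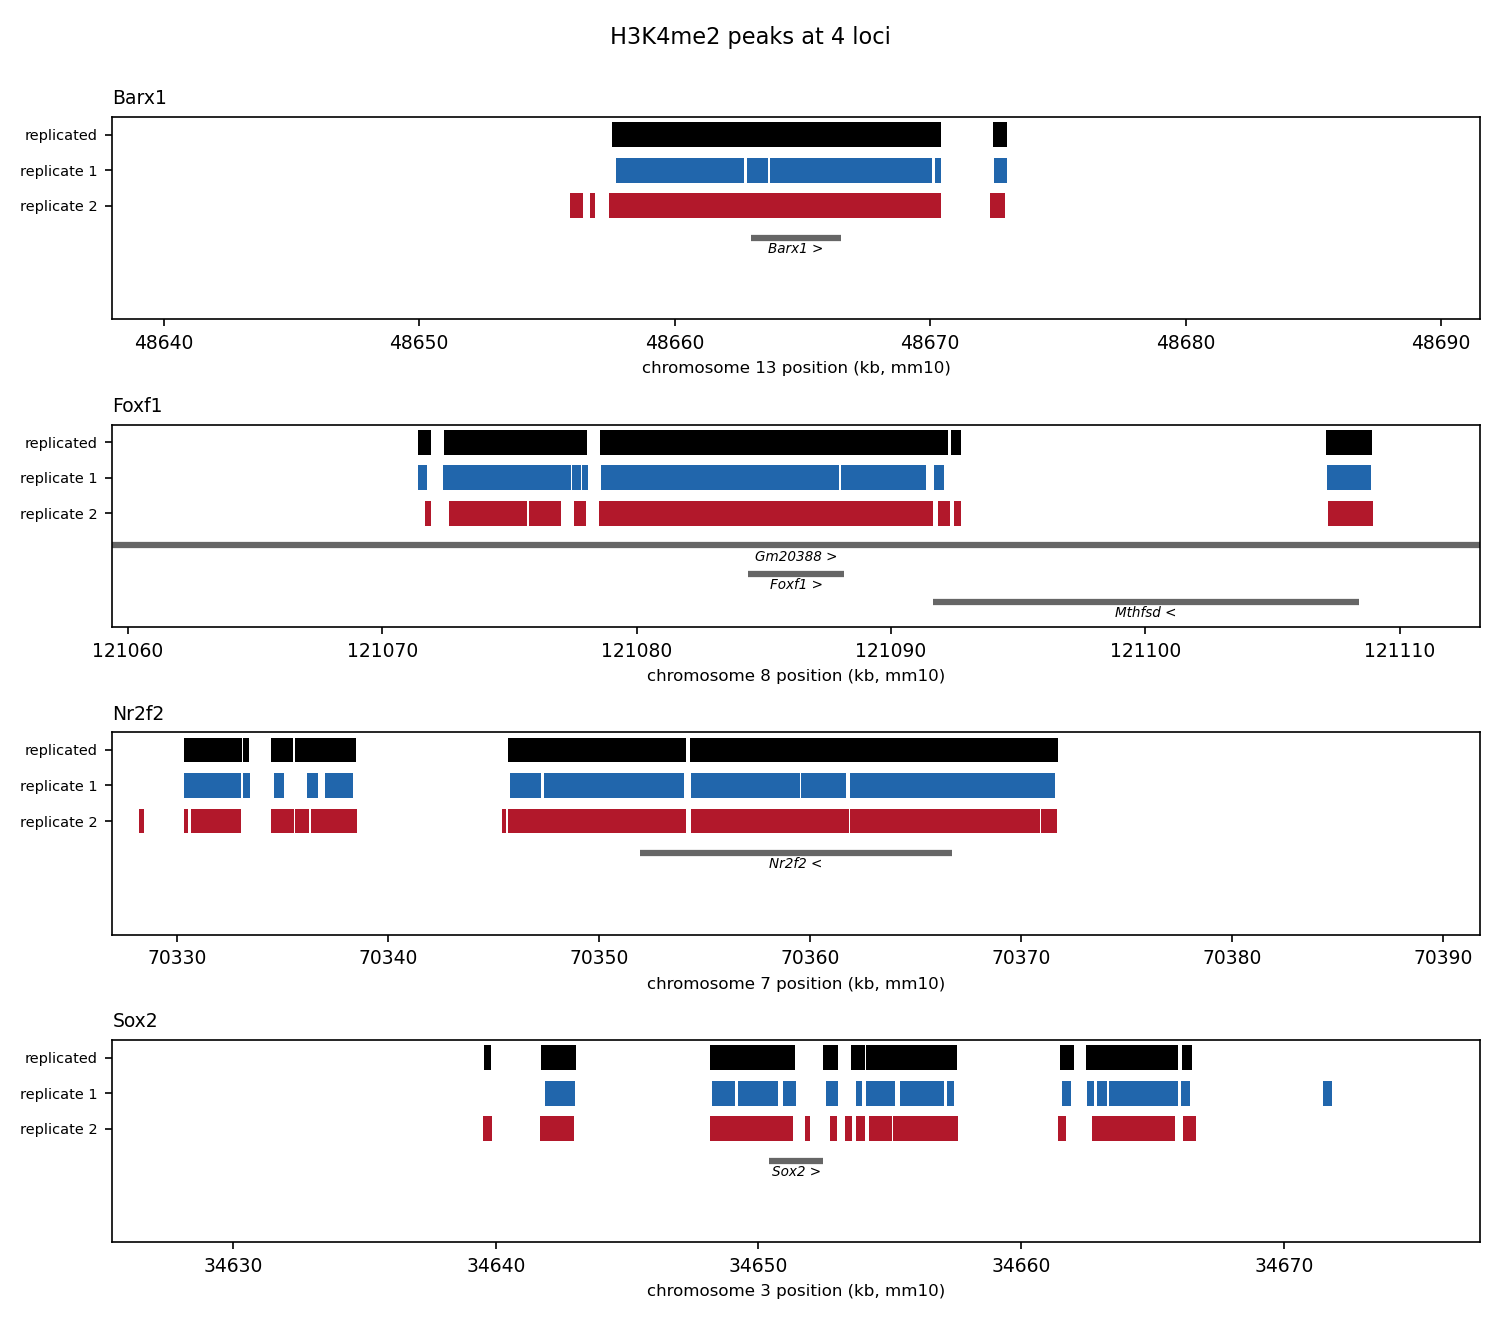
Peaks of the replicated list (black), replicate 1 (blue) and replicate 2 (red) around Barx1, Foxf1, Nr2f2 and Sox2, with gene spans in grey and position in kb (mm10) on each horizontal axis. A replicated peak of 12.9 kb spans Barx1, another of 13.7 kb spans Foxf1 and another of 17.4 kb covers most of Nr2f2, while Sox2 lies among 9 narrower peaks.

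At Barx1 a single replicated peak ran from 48657539 to 48670437 on chromosome 13, over the whole gene, with a fold enrichment of 17.6. At Foxf1 a peak of 13.7 kb ran from 121078563 to 121092219 on chromosome 8, with a fold enrichment of 21.8, and it also reached into the neighbouring Mthfsd. At Nr2f2, which encodes the nuclear receptor COUP-TFII, a peak of 17.4 kb ran from 70354334 to 70371739 on chromosome 7. The widest peak outside the Hox clusters, singled out after its value was seen, was 20.8 kb at Ptch1, the hedgehog receptor gene of the mesenchyme list (chromosome 13, 63553366 to 63574131).

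Every gene of the smooth muscle list carried H3K4me2 at its promoter, 17 of 17 against 65.0% in matched lists (adjusted p = 0.00107, permutation). These genes encode the contractile apparatus and its regulators, and many have promoters poor in CpG. Tpm1, which encodes an actin-binding tropomyosin, had the most covered sequence, 9.98 kb (9.49 ± 0.697 kb across replicates, SD, n = 2). Srf, the transcription factor of the contractile programme, had 6.10 kb, Myl9 5.98 kb and Tpm2 5.89 kb. The list's median was 3.98 kb against 1.70 kb (adjusted p = 0.0032, permutation), and 3.42 ± 0.862 kb across replicates. Distal peaks averaged 1.82 per gene against 0.537 (adjusted p = 0.0112, permutation), or against 0.677 with territory matched (adjusted p = 0.0480, permutation). All 3 calls ended when only peaks at or above the median fold enrichment were kept, where the adjusted permutation p-values were 0.0730, 0.546 and 1 in the order given.

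Genes of the foregut epithelium, which will line the stomach, also stood above matched lists in all 3 measures. All 26 of 26 had a promoter peak against 73.9% in matched lists (adjusted p = 0.00107, permutation). The median covered was 4.65 kb against 2.13 kb (adjusted p = 0.0016, permutation), and 4.13 ± 0.932 kb across replicates (SD, n = 2). The pioneer factor genes Foxa1 (chromosome 12, 57540628 to 57546916) and Foxa2 (chromosome 2, 148042877 to 148046969) had 12.3 and 11.5 kb covered. The endodermal regulator Gata6 had 11.6 kb, and Shh, the hedgehog ligand that endoderm sends to mesenchyme, 10.5 kb. Distal peaks averaged 3.27 per gene against 0.641 (adjusted p = 0.0016, permutation), with 13 near Gata4, which tied for ninth place among all genes. The random lists were not matched on gene class, and several members are transcription factors. Among family genes on none of the lists, Klf genes had a median of 4.30 kb covered and 1.29 distal peaks per gene. Sox genes had 3.87 kb and 3.14, and Fox genes 2.80 kb and 2.19. In these 2 measures a foregut trait cannot be told apart from a trait of gene class. Sox2, the foregut and stomach regulator (chromosome 3, 34650405 to 34652461), had 9.11 kb covered and a promoter peak with a fold enrichment of 11.6; it was singled out after its values were seen. When only peaks at or above the median fold enrichment were kept, the promoter share was 53.8% against 67% and the median covered 834 bp against 1825 bp, below the matched lists without passing the test (adjusted permutation p = 0.130 and 0.0528).

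**Figure D2:**
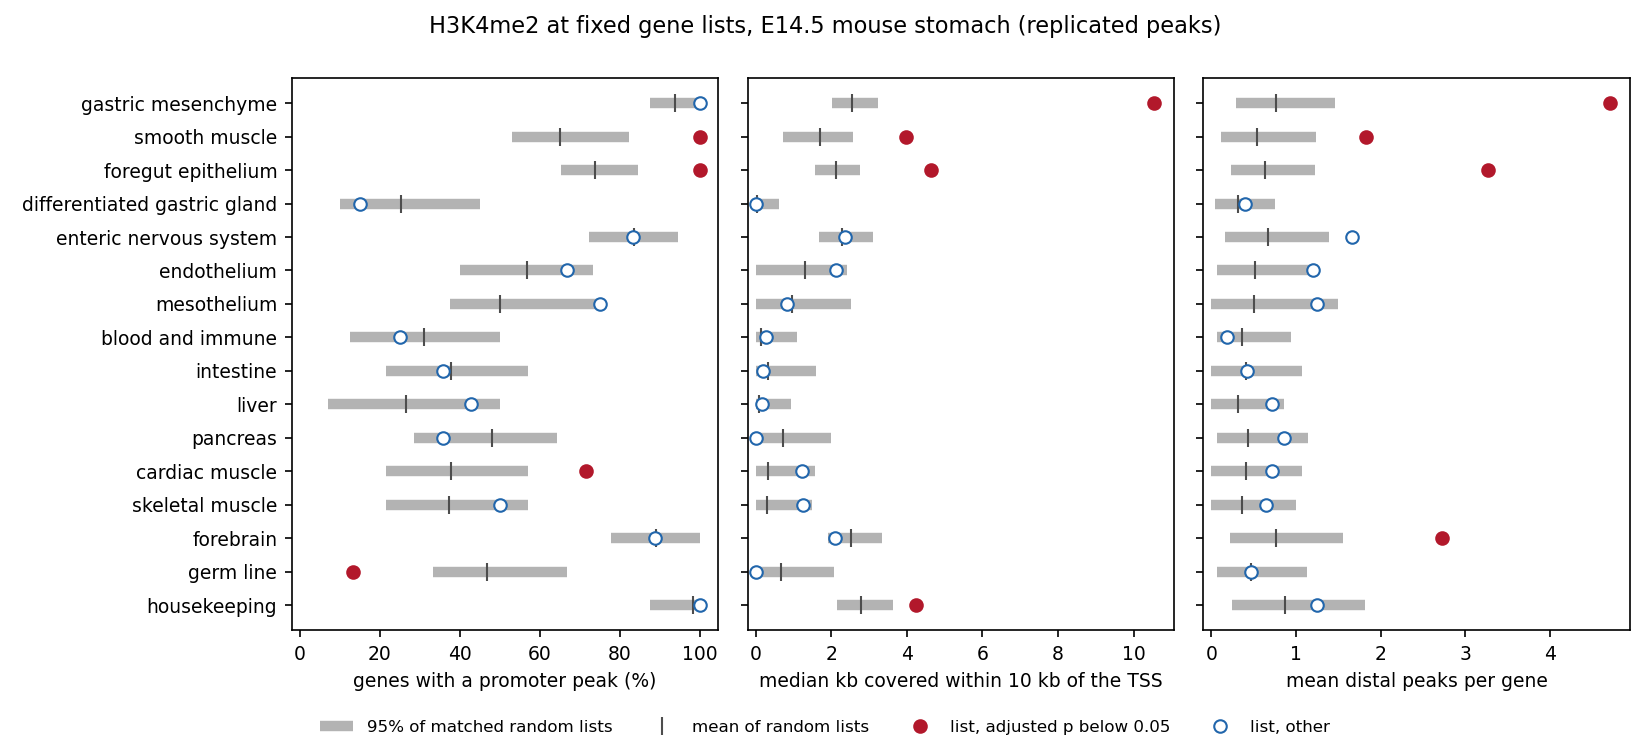
Share of genes with a promoter peak (%), median kb covered within 10 kb of the TSS and mean distal peaks per gene for the 16 fixed lists in the replicated list, with grey bars for 95% of 10000 matched random lists, ticks for their mean, red points for adjusted permutation p below 0.05 and open points for the rest. Gastric mesenchyme lies farthest to the right in covered kb (10.5) and distal peaks (4.71), and germ line is the 1 list below the range of its matched lists in promoter share (13.3%).

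Hox genes, whose order along each cluster follows the body axis, were marked in their anterior part. Hoxb4 (chromosome 11, 96318267 to 96321638) had the broadest cover of all genes, 20.0 kb, within the widest peak of the list, 31.4 kb from 96298258 to 96329705, which spans Hoxb4 and Hoxb5 and reaches into Hoxb3 and Hoxb6. Hoxa5 (chromosome 6, 52201754 to 52204587) had 19.3 kb, Hoxa2 18.2 kb, Hoxb6 17.0 kb and Hoxb2 14.0 kb. A second peak of 25.1 kb ran from 52156612 to 52181718 on chromosome 6, from Hoxa1 into Hoxa3. Within 2 kb of the TSS, the 15 genes of paralog groups 1 to 5 had a mean of 2.88 ± 1.33 kb covered (SD over genes) and the 16 genes of groups 9 to 13 had 0.477 ± 0.590 kb. The difference of 2.4 kb had a two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, and neighbouring Hox genes are not independent. The resamples did not keep genes within their cluster, and the groups differ in cluster make-up. HoxA and HoxB each gave 5 genes to groups 1 to 5, but 4 and 2 genes to groups 9 to 13. The pooled difference and its p-value thus also hold differences between clusters. Group 1 to 5 means were 2.60 kb in replicate 1 and 2.90 kb in replicate 2, and group 9 to 13 means were 0.364 and 0.538 kb.

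The 8 genes of groups 6 to 8 had a mean of 2.59 kb. Within groups 1 to 5, HoxA averaged 3.83 kb, HoxB 3.45 kb, HoxC 1.22 kb and HoxD 1.43 kb, and the clusters were not tested against each other. Within groups 9 to 13 the means were lower in each cluster: HoxA 0.41 kb, HoxB 1.12 kb, HoxC 0.25 kb and HoxD 0.51 kb. In HoxD the order was less clear, with 1.36 kb at Hoxd1, 1.60 kb at Hoxd8 and 1.34 kb at Hoxd9. These means depend on the annotated TSS: Hoxd3 and Hoxd4 start at 74711927 and 74711929 on chromosome 2 and share a window with 1.47 kb covered, and the 5'-most TSS of Hoxa3, at 52213336 on chromosome 6, lies between Hoxa6 and Hoxa7. The posterior end was not empty, as 9 of its 16 genes had some cover. Hoxb9 had 1.84 kb, Hoxd9 1.34 kb, Hoxa13 1.19 kb, Hoxd13 1.00 kb and Hoxc13 0.861 kb, and Hoxa9, Hoxa11, Hoxc9, Hoxc11, Hoxc12, Hoxd10 and Hoxd11 had 0 kb. The 5'-most TSS of Hoxc5 is annotated at 102967443 on chromosome 15, beside that of Hoxc10 at 102966796, and both genes had 0.376 kb.

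Genes of mature gastric glands were mostly unmarked. Of 20 genes in this list 3 had a promoter peak, 15% against 25.2% in matched lists (adjusted p = 0.603, permutation). Atp4b, a subunit of the acid pump, Gif, which encodes gastric intrinsic factor, and the pepsinogen genes Pga5 and Pgc had no promoter peak. Muc1, a mucin of many epithelia, had 6.56 kb covered, Mucl3 3.74 kb, the acid pump gene Atp4a 1.44 kb and Sst 1.13 kb. The list's median cover was 0 kb, and distal peaks averaged 0.40 per gene against 0.311 (adjusted p = 0.708, permutation).

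Lists of the other cell types of the embryonic stomach were not called in any of the 3 measures in the replicated list. In the enteric nervous system list, 15 of 18 genes had a promoter peak, with 15 kb covered at Hand2, a factor of neurons and mesenchyme, 7.19 kb at the receptor gene Gfra1, 6.42 kb at Erbb3 and 6.09 kb at Ednrb, and no replicated promoter peak at Phox2b, Plp1 or S100b. Its distal peaks averaged 1.67 per gene against 0.670 (adjusted p = 0.0550, permutation), and its median cover was 2.37 kb. Its distal peaks were called in 4 of 10 alternatives, those of the endothelial list in 2 of 10, and the promoter share of the mesothelial list in 2 of 10. In the endothelial list 10 of 15 genes were marked, with 4.75 kb at Sox18, 4.67 kb at Fli1, 3.50 kb at Sox17 and 3.01 kb at Egfl7, and no replicated promoter peak at Pecam1, Cdh5, Tie1 or Emcn. Phox2b, Pecam1, Tie1 and Gpm6a had a promoter peak in replicate 2 but not replicate 1, with a fold enrichment of 2.69, 3.46, 4.38 and 4.22. In the mesothelial list 6 of 8 were marked. Wt1, a regulator of the mesothelium, had 9.31 kb covered in the replicated list, but 2.71 kb in replicate 1 and 10.1 kb in replicate 2. Krt7 had 4.60 kb, and Upk3b and Gpm6a had no promoter peak in the replicated list. In the single lists, 7 of the 8 genes were marked in replicate 1 and 8 in replicate 2 and in the pooled list, with Upk3b in each. In the blood and immune list 4 of 16 were marked, among them the erythroid genes Klf1 (5.10 kb) and Gypa (1.46 kb), while Ptprc, Cd3e, Cd19 and Csf1r had no promoter peak.

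Among lists of other organs, the germ line list stood below its matched lists. A promoter peak was present at 2 of 15 genes, 13.3% against 46.8% (adjusted p = 0.00107, permutation), and Ddx4 (a peak in replicate 2 alone), Sycp3, Tex101 and Prm1 had none. Tnp2, a sperm chromatin gene without a promoter peak, still had 6.04 kb covered within 10 kb of its TSS, and Gdf9 had 2.13 kb. This window also counts peaks at neighbouring genes, so the cover cannot be given to these genes themselves. Cardiac muscle stood above its matched lists in promoter share only, 10 of 14 genes or 71.4% against 37.8% (adjusted p = 0.0152, permutation). Myl3 had 4.73 kb covered, Tnni3 3.68 kb, the pacemaker channel gene Hcn4 2.91 kb and Myl4 2.43 kb, whereas Myh6, Myh7, Nppa and Tnnt2, abundant in working heart muscle, had no replicated promoter peak. The promoter peak of Myl3 also lay within 1000 bp of a TSS of Pth1r, so it cannot be given to Myl3 alone. Myl4 had a peak shared in this way with Cdc27 and another that was not shared. The cardiac call held in 3 of 10 alternatives, and the adjusted permutation p reached 1 without matching on CpG class.

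Forebrain genes had more distal peaks than matched genes, 2.72 per gene against 0.761 (adjusted p = 0.0032, permutation). With territory matched, the comparison was 0.968 per gene (adjusted p = 0.00427, permutation). Their promoters (16 of 18 marked) and median cover (2.10 kb against 2.52 kb) were not called, with 3.95 kb at Otx1, 3.58 kb at Neurod2 and 3.54 kb at Foxg1, and no replicated promoter peak at Neurod6 or Otx2 (in replicate 1 but not replicate 2). The promoter share was called in 1 of 10 alternatives and the median cover in 2 of 9, each time below matched lists. The call on distal peaks ended among peaks at or above the median fold enrichment (adjusted permutation p = 0.0608).

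Intestine, liver, pancreas and skeletal muscle were not called in any of the 3 measures in the replicated list. In the intestinal list 5 of 14 genes had a promoter peak, with 5.64 kb at Satb2, 2.76 kb at Cdx1 and 2.29 kb at Cdx2, both homeobox regulators of the intestine, and no promoter peak at the enterocyte genes Fabp2, Alpi, Sis and Lct. Replicate 1 had promoter peaks at 3 genes of the list and replicate 2 at 7, so not all of the 5 had a promoter peak in replicate 1. Vil1, Isx, Krt20 and Cdh17 had a promoter peak in replicate 2 but not replicate 1, with fold enrichments of 3.84, 3.46, 3.32 and 3.32. In the liver list 6 of 14 were marked, with 7.78 kb at Hnf1a and 2.91 kb at Apoh, and no promoter peak at Alb, Apob, Serpina1a or Ahsg. In the pancreas list 5 of 14 were marked, with 4.34 kb at Nkx6-1 and 2.74 kb at Nkx2-2, and none at Cpa1, Ins1, Ins2 or Gcg. In the skeletal muscle list 7 of 14 were marked, with 2.70 kb at Ckm and 2.43 kb at Pax3, and none at Myog, Acta1, Mymk or Tnnt3. All 16 housekeeping promoters were marked, and their median cover of 4.25 kb was above the 2.78 kb of matched lists (adjusted p = 0.0112, permutation). Across replicates it was 3.85 ± 0.322 kb (SD, n = 2), with 7.92 kb at Polr2a and 4.98 kb at Actb, and the call ended with a window of 5 kb (adjusted permutation p = 0.207).

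Of the replicated peaks, 15112 (43.1%) were distal to protein-coding TSSs. The strongest lay in an exon of Klhl31 (chromosome 9, 77654913 to 77656159), 19 kb from its TSS, with a fold enrichment of 47.9. The next lay 6.40 kb from 1520401A03Rik (chromosome 17, 23698940 to 23700568; 44.4) and 182 kb from Mkln1 (chromosome 6, 31215941 to 31218945; 43.5), the latter within 1000 bp of a noncoding TSS. A strong peak in an intron of Tns3 (chromosome 11, 8621682 to 8625399) had a fold enrichment of 41.7, and 1 that lay 76.2 kb from Hmga2, a chromatin gene of embryonic tissues, had 41.0. The other 5 of the 10 strongest had Cacng6, Macf1, Cbx8, Dhx15 and Plxnb2 as nearest genes, with fold enrichments from 40.7 to 42.2. Those nearest to Cacng6 and Dhx15 also lay within 1000 bp of a noncoding TSS, and the former had its summit in an exon of Cacng8. The CpG observed/expected ratio of the 10 ran from 0.53 to 0.89. Most distal peaks per gene were found at the chromatin genes Chd2 and Gse1, with 19 each, at Foxp1 with 18 and at Bcor with 16. Of all distal peaks 1748 (11.6%) lay within 1000 bp of a noncoding TSS, and their median width was 604 bp against 1478 bp for the other peaks.

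Among 18 consensus motifs searched in 15107 distal peaks, 11 were more frequent than in GC-matched windows and 1 was less frequent. The largest ratio belonged to CTCF, a factor of chromatin loops, in 2.23% of peaks and 0.304% of windows, a log2 ratio of 2.87 (adjusted p = 3.75e-55, Fisher's exact). The forkhead consensus FOX was present in 7.18% of peaks and 3.81% of windows, a log2 ratio of 0.91 (adjusted p = 3.15e-37, Fisher's exact). The E-box CAGCTG, bound by basic helix-loop-helix factors, was in 29.3% against 23.5% and TEAD in 22.0% against 17.8%, both with a log2 ratio of 0.31. NFI had a log2 ratio of 2.42, from 16 peaks and 3 windows, and ETS 1.69, from 42 peaks and 13 windows. The ETS string holds a CpG, and windows were matched on GC content but not on CpG. Its excess cannot be told apart from a difference in CpG content. CTCF, FOX, E-box, TEAD, NFI and ETS kept their direction and their call against windows 2000 bp beside each peak, which were not matched on GC content. For the GC-rich strings of CTCF, E-box, NFI and ETS, a difference in base composition could give the same direction, so this adds no separate support. Against those windows the log2 ratio was 2.83 for CTCF, 0.38 for FOX, 0.72 for E-box and 0.10 for TEAD. Among the 2552 distal peaks at or above the median fold enrichment, NFI, ETS and E-box were not called by Fisher's exact test. There NFI was in 4 peaks and 0 windows, too few to test closely, ETS in 6 peaks and 4 windows, and E-box in 27.2% of peaks and 25.8% of windows, a log2 ratio of 0.07.

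Other motifs depended on the background. Against GC-matched windows the log2 ratio was 0.57 for POU, 0.54 for homeobox, 0.24 for NKX2, 0.22 for SOX and 0.05 for GATA, all called by Fisher's exact test, the last with an adjusted p = 0.0140. Among distal peaks at or above the median fold enrichment NKX2 (0.24), SOX (0.19) and GATA (0.14) were not called by Fisher's exact test. Beside the peak, GATA (−0.33), homeobox (−0.34) and NKX2 (−0.14) were less frequent in peaks than in windows, and POU (−0.06) and SOX (0.01) were not called. Those windows were not matched on GC content, so such values cannot be told apart from a difference in base composition. MEIS was less frequent in peaks than in GC-matched windows, with a log2 ratio of −0.27 (adjusted p = 9.88e-06, Fisher's exact). It was called in 4 of 8 alternatives, and beside the peak and in the pooled list it was not. GATA was called in 5 of 8 alternatives, 1 of them in the reverse direction beside the peak, and POU in 5 of 8. In replicate 2 alone neither was called. AP-1, SRF, HNF4, HNF1, RUNX and PHOX were not called against GC-matched windows in the main setting. Over 8 alternatives, windows beside the peak among them, AP-1 was called in 3, SRF, HNF1 and RUNX in 2 each, PHOX in 1 and HNF4 in 0. Beside the peak, RUNX was in 6.80% of peaks and 10.4% of windows, a log2 ratio of −0.61 (adjusted p = 6.84e-27, Fisher's exact), and SRF (−0.27) and PHOX (−1.25) were also less frequent in peaks.

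**Figure D3:**
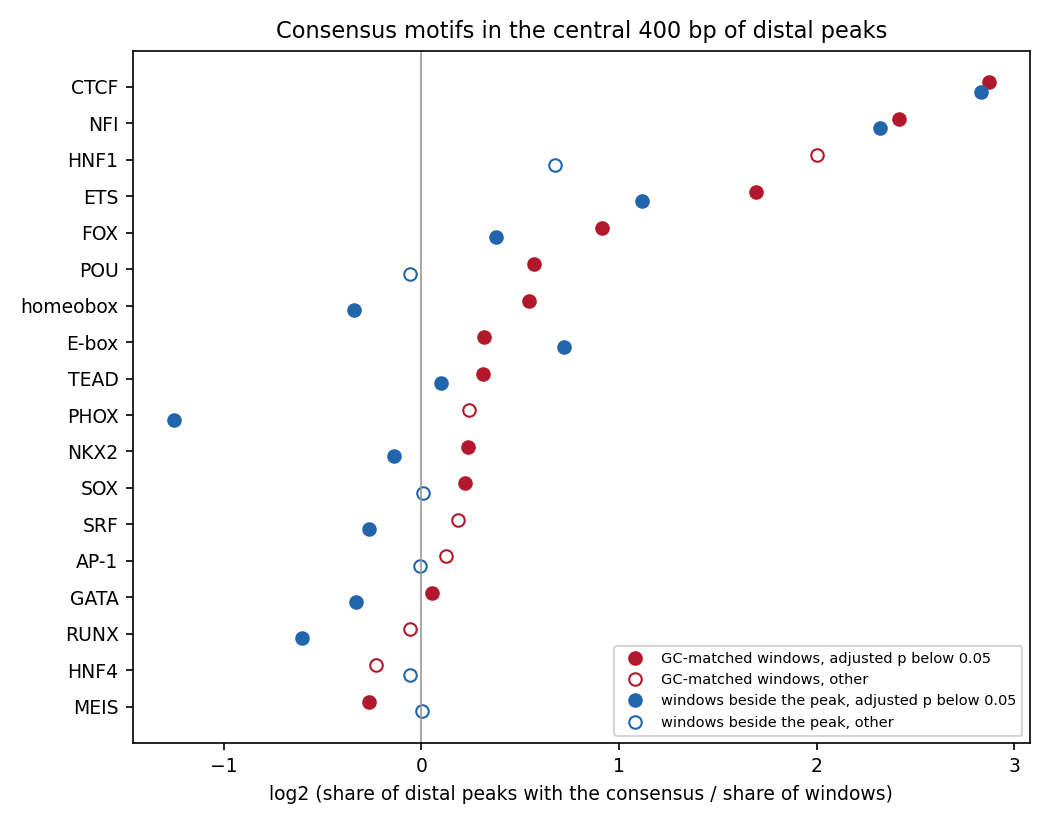
Log2 ratio of the share of distal peaks with each of 18 consensus motifs to the share of windows. Red points are against GC-matched windows and blue points against windows beside the peak, which were not matched on GC content. Filled points have an adjusted p below 0.05 by Fisher's exact test. CTCF lies at 2.87 and 2.83 on both backgrounds and FOX at 0.91 and 0.38, while GATA and homeobox lie on opposite sides of 0.

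Across the genome, H3K4me2 concentrated at promoters. Summits of 18476 of 35084 replicated peaks (52.7%) lay in a promoter, against 4.04 ± 0.101% (SD) in random placements, 13 times as many. Exons held 3.97% against 2.87%, introns 19.7% against 35.4% and intergenic sequence 23.6% against 57.7%. Each class had a two-sided permutation p = 0.0198, the smallest that 100 placements can give. The exon call ended among peaks at or above the median fold enrichment (2.98% against 2.91%) and with a promoter window of 2500 bp (2.41% against 2.26%). Promoter peaks were wider than intergenic and intronic ones, with medians of 1441, 657 and 595 bp.

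Nearly every CpG-rich promoter was marked and few CpG-poor ones were. Of genes with a promoter of high CpG class 6650 of 6683 had a peak, 99.5% (95% Wilson interval 99.3 to 99.6%; replicates 99.5 ± 0.159%, SD, n = 2). Of the intermediate class 6371 of 6727 did, 94.7% (94.1 to 95.2%; replicates 94.9 ± 0.526%), and of the low class 1827 of 8528, 21.4% (20.6 to 22.3%; replicates 22.5 ± 2.2%). In all, 14848 of 21938 protein-coding genes had a promoter peak, 67.7%.

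Strong regions were shared by both replicates and weak ones often were not. Of replicate 1 peaks 36131 of 41568 (86.9%) touched a replicate 2 peak, against 3.54% when placed at random, and 33859 of 54864 replicate 2 peaks (61.7%) touched replicate 1, against 2.75%. The base-pair Jaccard index was 68.7% against 0.899%. Each had a one-sided permutation p = 0.0099, the smallest that 100 placements can give. With each replicate's peaks in 10 equal bins by fold enrichment, every peak in the upper 4 bins of replicate 1 touched replicate 2, and of the lowest bin 60.4% and the next 51.9% did. For replicate 2 the shares were 100% in the upper 3 bins and 18.6% in the lowest and 16.6% in the next.

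**Figure D4:**
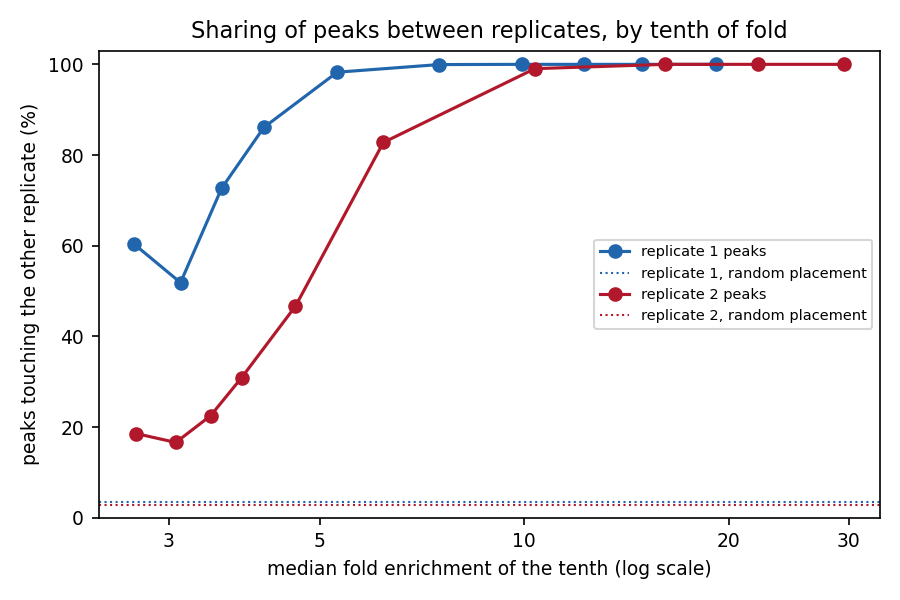
Share of each replicate's peaks that touch the other replicate (%) in 10 equal bins by fold enrichment, at the median fold enrichment of the bin on a log axis, with dotted lines for random placement. Sharing is 60.4% in the lowest bin, 51.9% in the next and 100% in the highest in replicate 1, and 18.6%, 16.6% and 100% in replicate 2, far above 3.54% and 2.75% at random.

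The 21005 peaks of replicate 2 alone had a median fold enrichment of 3.46 and a width of 231 bp, and 13.2% had their summit in a promoter. Shared replicate 2 peaks had medians of 12.9 and 984 bp, with 57.1% in promoters. The 5437 peaks of replicate 1 alone had medians of 3.19 and 232 bp, with 11.3% in promoters. Over 30674 replicated peaks that touch both replicates, fold enrichment correlated with Spearman's rho = 0.857 and Pearson's r = 0.866 on the log2 scale, across peaks, which are not independent replicates. Rho was 0.574 among peaks at or above the median fold enrichment. Fold enrichment was higher in replicate 2 at 86.9% of these peaks, with a median ratio of 1.51. Of pooled peaks 35084 of 53426 (65.7%) were in the replicated list, and the 18342 dropped had a median fold enrichment of 2.91 against 11.2 for those kept. All 30588 pooled peaks that overlap both replicates by at least 1/2 of either peak were kept, and 4410 replicated peaks (12.6%) did not touch both replicates.

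Peak density differed among chromosomes. Autosomes ranged from 9.38 peaks per Mb on chromosome 14 to 22.4 on chromosome 11, with a median of 14.4. Chromosome X had 5.75 peaks per Mb, below every autosome and 0.401 of their median, in tissue pooled from both sexes. The ratio was 0.398 in replicate 1 and 0.335 in replicate 2. Chromosome Y had 4 peaks.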

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

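The count of peaks outside the analysed chromosomes was looked for after the files had been seen. The replicated list held 14 peaks on contigs outside the assembled chromosomes, which no comparison of the report uses, with a median fold enrichment of 6.32. They lie on 6 contigs. The contig assigned to chromosome X held 6 of them over 4.34 kb, with a median fold enrichment of 8.20. Replicate 1 had 13 such peaks and replicate 2 also had 13. No explanation was tested.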

How the results depend on the processing

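The alternatives were fixed before the data were examined, except peaks that touch both replicates, the 5'-most TSS alone, the mean over every Hox TSS and the alternatives for chromosome X, which were chosen after the data had been seen. Of 1084 alternative values, those of the main results were labelled the same in 76 cases and moved in 21. The label allows for change: a count could differ within a fixed ratio, and a tested value needed only the same direction and call. Values without a test had to lie within the replicate SD or the interval over peaks. The promoter share of summits, 52.7% as reported, ran from 36.9% to 79.5% and was labelled the same throughout. So were 3764 peaks in replicate 1 alone, beside 5437 as reported. For single lists, motifs, genes and classes, 807 stayed the same, 119 moved, 24 gained a call, 28 lost it and 9 changed direction with a call in at least 1 setting; values called in neither setting were counted as the same. Mesenchyme breadth was called in 9 of 9 alternatives and its distal peaks in 10 of 10, and the Hox difference in 8 of 8. Keeping only peaks at or above the median fold enrichment removes peaks by construction: 17578 replicated, 20805 and 27641 in replicates 1 and 2 and 26739 pooled peaks remained. It left 110 peaks in replicate 1 alone and 7183 in replicate 2 alone, rho = 0.574, 2 called lists for distal peaks, 6 called motifs, a ratio of 0.30 for chromosome X, and 85.5 percentage points between high and low CpG classes (78.1 as reported). The foregut epithelium then lay under its matched lists without being called (53.8% of promoters, adjusted permutation p = 0.130; median of 834 bp, 0.0528). With overlap of 1/2 of both peaks 14715 replicate 1 peaks were unshared, and with a −log10 q of at least 2 rho was 0.840. Pooled peaks that meet an overlap rule with both replicates were 57.7% at 1 bp, 57.3% at 1/2 of either and 47.7% at 1/2 of both peaks. The CpG difference was 75.2 in the pooled list, 75.5 with a window of 2500 bp and 75.6 to 78.5 with 1 replicate left out, and the ratio for chromosome X 0.335 to 0.398. Without matching on CpG class, 7 lists differed in promoter share. Beside the peak the log2 ratio changed sign for GATA (−0.33), homeobox (−0.34), NKX2 (−0.14), MEIS (0.0028), SRF (−0.27), PHOX (−1.25) and POU (−0.057), and also for AP-1 (−0.0059), which was called in neither. Windows beside the peak were not matched on GC content, so these sign changes cannot be told apart from a difference in base composition. The cause was not tested. Read depth is unknown, so whether the weak peaks of replicate 2 reflect depth could not be tested.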

Other observations

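The gene families, their tests without listed genes and the test of cardiac tissue were chosen after the peak lists had been seen. Collagen genes, which build the extracellular matrix, had a median of 3.17 kb covered within 10 kb of the TSS over 44 genes, against 1.26 kb in lists matched on CpG class (adjusted p = 0.0048 over 24 families, permutation). Col1a1 had 8.92 kb, Col12a1 5.70 kb and the basement membrane gene Col4a2 5.54 kb. Genes of the Klf family had 4.68 kb against 2.64 kb (adjusted p = 0.0048, permutation), with 11.4 kb at Klf3 and 8.25 kb at Klf5. The Sox family had 4.16 kb against 2.66 kb (adjusted p = 0.0120, permutation), with 8.99 kb at Sox4 and 8.52 kb at Sox6. Gata genes had 4.98 kb against 2.39 kb (adjusted p = 0.0230, permutation) and Fox genes 3.39 kb against 2.53 kb (adjusted p = 0.0096, permutation). These families share genes with the lists of the report: 3 of Klf, 5 of Sox, 3 of Gata and 8 of Fox. Without those genes Klf stayed above matched lists (4.30 kb against 2.70 kb, adjusted p = 0.0448, permutation), while Sox (3.87 kb against 2.73 kb over 14 genes, adjusted p = 0.131), Gata (4.01 kb against 2.70 kb over 3 genes, 0.388) and Fox (2.80 kb against 2.48 kb over 36 genes, 0.388) were not called by the same permutation test. With fewer genes tested, these lost calls do not show that the listed genes carried the result. The Slc6 transporters of neurotransmitters and amino acids were below matched lists, 1.14 kb against 2.09 kb (adjusted p = 0.0320, permutation).

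With territory matched, distal peaks were more frequent than in matched lists near Sox genes (3.05 per gene against 1.20, adjusted p = 0.0144, permutation), Fox genes (2.48 against 0.957, adjusted p = 0.0048, permutation) and Nkx genes (2.57 against 0.947, adjusted p = 0.0312, permutation). Without listed genes this held for Sox (adjusted p = 0.0456) and Fox (0.0048) in the same permutation test, and Wnt, not called with them (0.0516), was called (1.76 against 0.676, 0.0456). Nkx was not called over its 10 remaining genes (1.80 against 0.847, adjusted p = 0.182, permutation). Distal peaks were less frequent near the Cyp2 genes of drug and steroid metabolism (0.104 against 0.420, adjusted p = 0.0312, permutation). Of the keratin genes 13 of 49 had a promoter peak, and of the alpha and beta defensins (Defa and Defb genes) 0 of 64. Among single genes, Tbx2 had 13.1 kb covered, Irx5 11.4 kb, Tbx3 8.57 kb, Wnt5a 8.30 kb and Bmp7 8.22 kb.

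Promoters of 4 intestinal genes, Vil1, Isx, Krt20 and Cdh17, had a peak in replicate 2 alone. Greater sensitivity of replicate 2 is a candidate explanation. Matched lists held a mean of 0.455 such genes with an upper limit of 2, but the intestine was the highest of 16 lists and the adjusted permutation p over them was 0.0512, so this stays open. Intestinal tissue in replicate 2 stays open too: covered sequence within 10 kb of the list's genes was 302 bp higher in replicate 2, under the limit of matched lists (407 bp) but above their mean (190.0 bp, percentile 87.7), so the bound set in advance was too wide to exclude a small share. Fabp2, Alpi, Sis and Lct, abundant in mature enterocytes and on no other list, had no promoter peak in either replicate, which decides nothing for embryonic tissue.

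Distal peaks were more frequent near forebrain genes than near matched genes. The list stood at percentile 99.97 of lists matched on quintile of territory. As far as quintiles capture territory, this argues against the explanation that more of the genome lies nearer to these genes than to others. Differences within a quintile were not matched, and neither was gene class. Sox and Fox genes on none of the lists averaged 3.14 and 2.19 distal peaks, beside 2.72 for the forebrain list. Klf and Gata genes on none of the lists averaged 1.29 and 1.00. Whether gene class accounts for the excess was not tested. Whether these distal peaks are sites in use in the stomach stays open. Their median fold enrichment was 5.49 over 49 peaks, and 5.38 over the 113 peaks near gastric mesenchyme genes. Peaks near intestinal (6.29) and pancreatic (5.87) genes reached that level too, so the test decides nothing.

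Cardiac muscle genes had more promoter peaks than matched genes. Peaks that lie at a neighbouring gene's promoter could add to the count. Leaving them out removed Myl3 and gave 9 genes instead of 10, against a mean of 4.49 and a limit of 8 in matched lists. In a test added after the data had been seen the list stayed called without them (ratio to matched lists 2.02 instead of 1.89, adjusted permutation p = 0.0320), which argues against them as the whole cause, but 9 is less than 1 SD (1.48) above the limit, short of the margin set for excluding them. Cardiac tissue in the sample stays open. Of Myh6, Myh7, Nppa and Tnnt2, 1 gene (Myh7, in the pooled list alone, fold enrichment 3.76) had a promoter peak in any list, which decides neither way, and no gene of this list stands on another list.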
